A study of Mus musculus with 42 samples.

How the data were processed

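RNA-seq was carried out on 7 tissues of 6 mice: left and right atrium, left and right ventricle, left kidney, left lung and adrenal gland. Per the labels, 3 mice lacked an enhancer named musENH5 (KO) and 3 were wild type (WT), which gave 42 libraries in 14 groups of 3. The labels number the animals (KO201, KO203, KO205, WT215, WT221 and WT223), and a library is named here by its tissue and its animal. All animals were 9 weeks old and had spent about 16.5 h in hypobaric hypoxia at 280 to 290 mmHg, close to 8% oxygen. No group kept at normal pressure was analysed here. Per the labels, 1 KO and 1 WT mouse shared the chamber in each run, but the pairs are not named, so genotypes were compared without a pair term. Each organ had a sequencing lane of its own, so organ and lane cannot be told apart. Heart tissues were extracted by hand in Trizol and the other organs on an extraction robot, and the unstranded TruSeq libraries were read from 1 end. Reads of a gene and of an antisense partner could therefore not be separated. The labels name the adrenal as the right one in the protocol, while the tissue codes end in a letter that elsewhere marks the left side, so the side is left open here.

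The authors deposited, per the file headers, an expected count and a TPM for each of 142604 isoforms, in the output format of RSEM. Per the submitters' processing notes, STAR, RSEM and limma were used with the mouse build mm10; their versions and the annotation release are not given in the sources used here. RSEM divides reads that match several isoforms or near-identical genes, so values of paralogs, pseudogenes and small RNA copies are uncertain. The deposited expected counts were summed per gene over its isoforms (55401 genes) and rounded to whole numbers for the count tests. The deposited TPM values were summed per gene in the same way and used only in alternatives. Symbols and positions came from GENCODE vM21 on mm10, which named 55141 genes and left 260 without a name; 213 symbols belonged to more than 1 gene. The total expected count per library lay between 40.7 and 139 M (median 56.7 M), and the second deepest library held 84.8 M. At these depths counting error was on average small against the spread between animals. Over the 42 pairs of libraries of a group, the mean chi-square per gene (genes with 20 or more counts) was 13.4 to 820, where counting error alone gives about 1. Over all 861 pairs of libraries the lowest was 11.0, so no pair was a duplicate. Expression of Xist (at most 0.505 CPM) and Ddx3y (at least 43.9 CPM) was male in every library, so no sex term was fitted.

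Each tissue was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, the quasi-likelihood F-test and Benjamini-Hochberg adjustment over the genes tested, with calls at 0.05. Fold changes are log2 KO minus WT, with the standard error of the fit. CPM values are scaled by TMM within a fit, so levels from fits over different libraries differ in scale. Marker levels given for single libraries, as for the chamber markers, are scaled over all 42 libraries unless stated. Epas1 was also adjusted over the 7 tissues and tested by an exact two-sided permutation test of 3 against 3 animals, whose smallest possible p is 0.1. Effects shared by the tissues were tested with limma 3.58.1 on each animal's mean log2 CPM over the 7 tissues (prior count 2). Effects that differ between tissues were tested with edgeR as the interaction of genotype and tissue, with the animal as a block. Left and right chambers came from the same animals, per the labels, so these fits had the animal as a block.

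A total of 17 pathway lists and 16 cell type lists were tested in each tissue where at least 5 members passed the filter, which gave 203 combinations of list and tissue. The test was camera in limma with a preset correlation of 0.01, adjusted over the 203 combinations. Camera with an estimated correlation and fry stood beside it; fry tests whether a list's genes move one way on balance, or, as fry mixed, in either direction, and compares the list with no other genes. The pathway lists were HIF-2-linked targets, glycolysis and HIF-1-linked targets, HIF pathway components other than Epas1, genes around Epas1 on chromosome 17, oxidative phosphorylation, fatty acid oxidation, cardiac stress, extracellular matrix, catecholamine synthesis, steroid synthesis, renin and salt handling, interferon response, cell cycle, protein folding stress, immediate early genes, circadian clock and glucocorticoid response. The cell type lists were endothelial cells, lymphocytes, myeloid cells, neutrophils, red blood cells, thymocytes, adipocytes, brown adipocytes, cardiomyocytes, fibroblasts, smooth muscle cells and pericytes, kidney tubule cells, alveolar cells, airway cells, mesothelial cells, and Schwann cells and neurons.

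The groups, the tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Epas1 in every tissue, the genes around it with the smallest p, and per tissue up to 8 called genes each way by fold change, with a mean log2 CPM of at least 1, an ordinary symbol and no overlap of the genotypes. Where fewer than 3 genes were called, it named the 3 with the smallest p that met the other conditions, as not called. It also named the 10 smallest p of the interaction, the 4 members with the smallest p of a list past its test, some HIF-2-linked targets such as Vegfa, Epo, Edn1, Adm and Egln3, and for left against right chambers the 5 largest changes each way and chamber markers such as Bmp10. A few of the genes that the rule named are not reported here. Genes called in 3 or more tissues were to be named too, and there were none.

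The scripts were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed, 50 at each of 4 fold sizes. In the tissue fits a 16-fold change was recovered in 94% to 100% of its genes. A 4-fold change was recovered in 96% (left atrium), 98% (left ventricle), 60% (right atrium), 96% (right ventricle), 94% (kidney), 98% (lung) and 28% (adrenal gland). For a change of 2-fold the shares were 60%, 58%, 0%, 34%, 56%, 40% and 0% in the same order, and for 1.5-fold 26%, 8%, 0%, 2%, 8%, 8% and 0%. The tissue fits made at most 10 false calls. The animal means recovered 54%, 96%, 94% and 100% from the smallest to the largest fold, the interaction (changed in the lung) 0%, 10%, 66% and 96%, left against right atrium 10%, 54%, 96% and 100%, and left against right ventricle 48%, 92%, 100% and 100%. Each simulated library was drawn on its own, with no effect shared by the organs of an animal. The shares for the animal means therefore overstate recovery where the organs of an animal deviate together, as they did for several lists. A simulated list of 30 genes raised 1.5-fold had a camera p of 1.77e-34, and an unchanged list of 30 had 0.366. With an estimated correlation the camera p was 0.000154 and 0.362, and the fry p 0.000133 and 0.0672. Simulated genes were drawn independently, so this cannot show how often camera with a preset correlation calls lists of correlated genes.

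The alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), 1 fit over all 42 libraries, counts summed over tissues, a random animal effect, no animal block, WT animals only, and leaving out each animal in turn. Fits without the right atrium were added after the data were seen, because the library labelled right atrium KO205 stood apart.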

Results

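The series measured RNA in 42 libraries from 7 organs or heart chambers of 6 male mice after hypoxia, 3 without the enhancer musENH5 (KO) and 3 wild type (WT). The enhancer is described in the series as a hypoxia-sensitive one tied to EPAS1, whose mouse gene Epas1 encodes the oxygen-regulated subunit of the transcription factor HIF-2. Each tissue and genotype had 3 libraries. Total expected counts per library were 49.8 to 75.9 M in the adrenal gland, 50.4 to 78.1 in the left atrium, 51.0 to 79.9 in the right atrium, 45.8 to 80.7 in the left ventricle, 40.7 to 139 in the right ventricle, 48.98 to 71.5 in the kidney and 43.4 to 84.8 in the lung. The comparisons asked what the loss of the enhancer did to Epas1, to the genes around it and to the rest of the transcriptome in each tissue. The coordinates of the enhancer are not given in the sources used here, so the deletion itself was not checked. The library labelled right atrium KO205 had a ventricular profile, described with the heart chambers, and values without it stand beside many of the right atrial results.

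In WT animals Epas1 (ENSMUSG00000024140.10, chromosome 17, 86753700 to 86833410, plus strand, mm10) was highest in the lung, at 1897 ± 386 CPM (SD, n = 3; scaled over the 21 WT libraries). The ventricles followed, with 490 ± 62.3 CPM in the right and 458 ± 21.5 in the left. The atria held 311 ± 67.4 CPM on the right and 292 ± 44.5 on the left. The adrenal gland held 194 ± 6.34 CPM and the kidney 139 ± 8.22, so lung and kidney differed 13.6-fold. Epas1 differed between the 7 tissues by edgeR with the animal as a block (adjusted p = 4.21e-12 over 22270 genes). In the deposited TPM the lung held 814 ± 222 and the kidney 31.7 ± 1.11, again the highest and the lowest, but the order between them differed, with 78.7 ± 22.7 in the right atrium, 75.9 ± 5.18 in the right ventricle, 68.2 ± 5.71 in the left atrium, 67.6 ± 2.54 in the adrenal gland and 61.6 ± 14.3 in the left ventricle. Organ and sequencing lane cannot be told apart in these levels.

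Epas1 did not differ detectably between KO and WT in any of the 7 tissues. In the lung, where it was highest, it held 2388 ± 406 CPM in KO and 2946 ± 688 in WT (SD, n = 3 each, scaled within the lung), a log2 fold change of -0.30 ± 0.22 (SE). The kidney held 140.1 ± 2.10 CPM in KO and 142 ± 8.72 in WT. The left ventricle held 306 ± 14.3 and 300.2 ± 20.9 CPM, and the right ventricle 362 ± 53.9 and 357 ± 50.1. The log2 fold changes were -0.021 ± 0.093 in the kidney, 0.029 ± 0.11 in the left ventricle, 0.021 ± 0.17 in the right ventricle, -0.053 ± 0.13 in the left atrium and 0.094 ± 0.12 in the adrenal gland. In the right atrium it was 0.31 ± 0.28, and 0.14 without KO205. The edgeR p adjusted over the 7 tissues was 0.905 in each of them, and the exact two-sided permutation p lay between 0.3 in the lung and 0.9, where 0.1 is the smallest possible. The 95% intervals of the log2 fold change ran from -0.24 to 0.20 in the kidney, from -0.22 to 0.27 in the left ventricle and from -0.80 to 0.20 in the lung. A loss of Epas1 to a ratio below 0.848 in the kidney, or below 0.573 in the lung, therefore lay outside them. Averaged over the 7 tissues of each animal the difference was 0.0095 ± 0.106 (exact permutation p = 0.9), with 4 tissues higher in KO and 3 lower. In the adrenal gland the deposited TPM gave the other direction, with 56.6 in KO and 67.6 in WT.

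**Figure D1:**
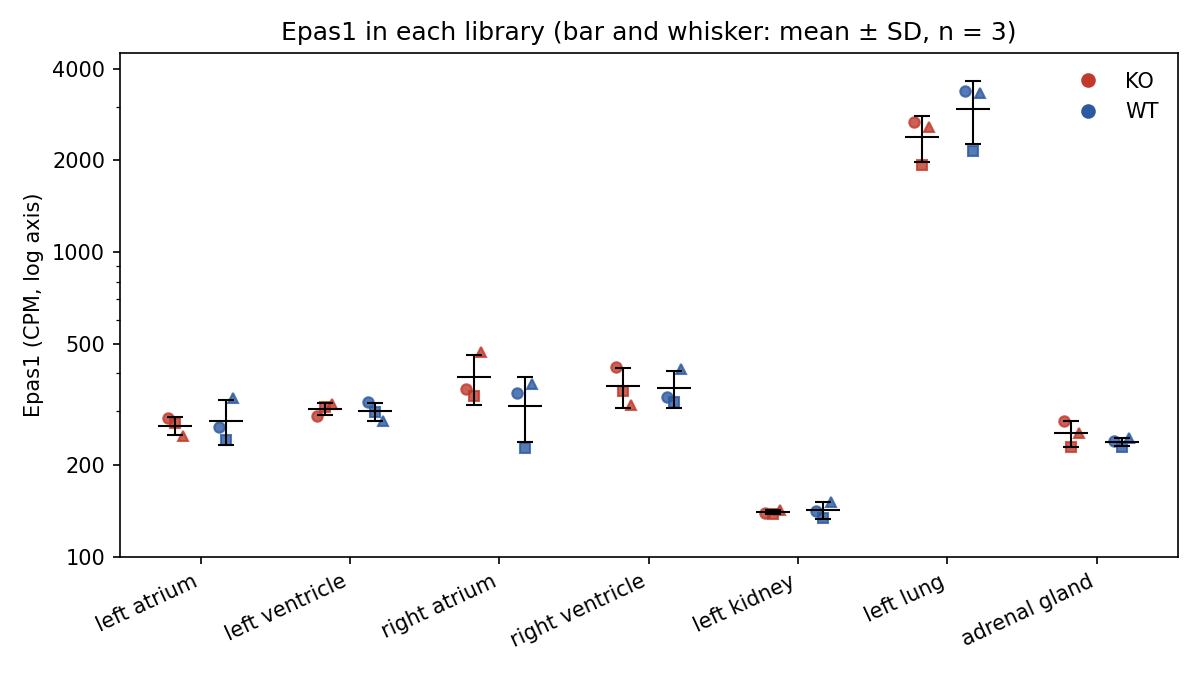
Epas1 in CPM (log axis, scaled within each tissue) for the 7 tissues, with KO libraries in red, WT libraries in blue, a marker shape per animal, and a bar and whisker for the mean and SD of 3 libraries. The KO and WT libraries overlap in every tissue, and the lung stands highest with means of 2388 CPM in KO and 2946 in WT.

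Genes around Epas1 on chromosome 17 were tested because an enhancer can act on several neighbours. Between 13 and 15 of them passed the filter in a tissue, and edgeR called 0 of them, over all genes or adjusted over the list alone. The smallest unadjusted p in the adrenal gland belonged to Ttc7, with a log2 fold change of 0.38 ± 0.15 (SE). In the lung it was Msh6 at -0.29, in the left atrium Rhoq at -0.21 ± 0.14, in the left ventricle Calm2 at -0.29 and in the kidney Mcfd2 at 0.14. As a list, these genes stood lower in KO in the right atrium (median -0.26, 11 of 14 lower, camera adjusted p = 0.0262, and adjusted p = 0.702 with an estimated correlation). That call was lost without KO201 (-0.23), KO203 (-0.25), WT215 (-0.29) or WT221 (-0.19).

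HIF-2-linked targets, genes that HIF-2 is known to act on, stood slightly higher in KO than in WT in 5 of the 7 tissues by camera with a preset correlation. Their median log2 fold change was 0.12 in the left atrium, 0.29 in the right atrium, 0.12 in the right ventricle, 0.12 in the kidney and 0.23 in the lung. The adjusted p was 0.0114, 0.00285, 0.019, 0.00276 and 0.00697 in the same order. With an estimated correlation the adjusted p was between 0.702 and 0.749, so none of the 5 held. Endothelial genes, a list that shares Kdr and Cdh5 with this one, were past camera as higher in KO in 4 of the same 5 tissues (medians of 0.084 in the left atrium, 0.36 in the right atrium, 0.21 in the right ventricle and 0.11 in the kidney; adjusted p = 0.702 to 0.821 with an estimated correlation), and in the lung their median was -0.0045. In the left ventricle the median of the HIF-2-linked targets was 0.055 and in the adrenal gland 0.093, with adjusted p of 0.244 and 0.63. Members with the smallest p were Ankrd37 in the kidney (0.73) and lung (1.62), Rgs4 in the kidney (0.41) and lung (0.57), and Adora2a (1.08, and 0.64 without KO205) and Cxcl12 (1.87, and 0.45 without KO205) in the right atrium. In the left atrium Rgs4 was at 0.32, and in the right ventricle Pdgfb was at 0.62. None of the 29 or 30 members was called by edgeR in these tissues, over all genes or adjusted over the list alone. Without a single animal the camera call was lost in the left atrium (median 0.044 without KO205, 0.074 without WT223), the right atrium (0.064 without KO205, 0.31 without WT223), the right ventricle (-0.048 without KO201, 0.088 without WT215, 0.054 without WT223), the kidney (0.078 without KO203, 0.12 without WT223) and the lung (0.11 without KO205, 0.12 without WT221).

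Of the targets chosen by name and reported here, none was called in any tissue by edgeR. Vegfa, the vascular growth factor gene, ranged from -0.13 in the adrenal gland to 0.70 ± 0.31 in the right atrium (0.35 without KO205), with -0.074 ± 0.17 in the lung and -0.10 ± 0.16 in the kidney. Epo, the erythropoietin gene, passed the filter in the kidney alone, at 1.12 CPM in KO and 0.596 in WT (log2 fold change 0.89 ± 0.60). Adm was at -0.93 ± 0.58 in the right atrium (-0.49 without KO205) and 0.36 ± 0.31 in the lung. Egln3, an oxygen-sensing hydroxylase gene, was at 0.60 ± 0.28 in the lung and -0.37 ± 0.24 in the left ventricle. Edn1 was at -0.42 ± 0.42 in the left atrium and 0.39 ± 0.88 in the lung. Glycolysis and HIF-1-linked targets had medians of -0.034 to 0.19 and passed camera in the lung (median 0.12, 20 of 29 higher), with Ldha at 0.31, Aldoc at 0.36, Bnip3 at 0.40 and Pdk1 at 0.30. That adjusted p was 0.00709, and adjusted p = 0.702 with an estimated correlation, and the call was lost without KO201 (0.13) or WT221 (0.065). The HIF pathway components other than Epas1 passed no test, with medians of -0.07 to 0.17.

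Across the 203 combinations of list and tissue, 60 were past camera with the preset correlation, 44 higher and 16 lower in KO. None of the 60 held with an estimated correlation (smallest adjusted p = 0.702), by fry (0.672) or by fry mixed (0.527). Of these 60 calls, 13 were made again in all 6 fits that left out 1 animal. In every one of the 60 the median, the mean and the test had the same sign. Member genes called by edgeR numbered 0 over all genes and 14 adjusted over the list alone. Adjustment over the list alone does not allow for the 203 combinations tested, so some calls of this kind can arise by chance. Renin and salt handling had medians of -0.095 to 0.096, interferon response -0.13 to 0.077, circadian clock -0.12 to 0.06, cardiomyocytes -0.13 to 0.29 and airway cells 0.22 in the lung, and none passed. Neutrophils were tested in 2 tissues, with medians of -0.13 and 0.53, and did not pass, and thymocytes had too few members in every tissue.

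**Figure D2:**
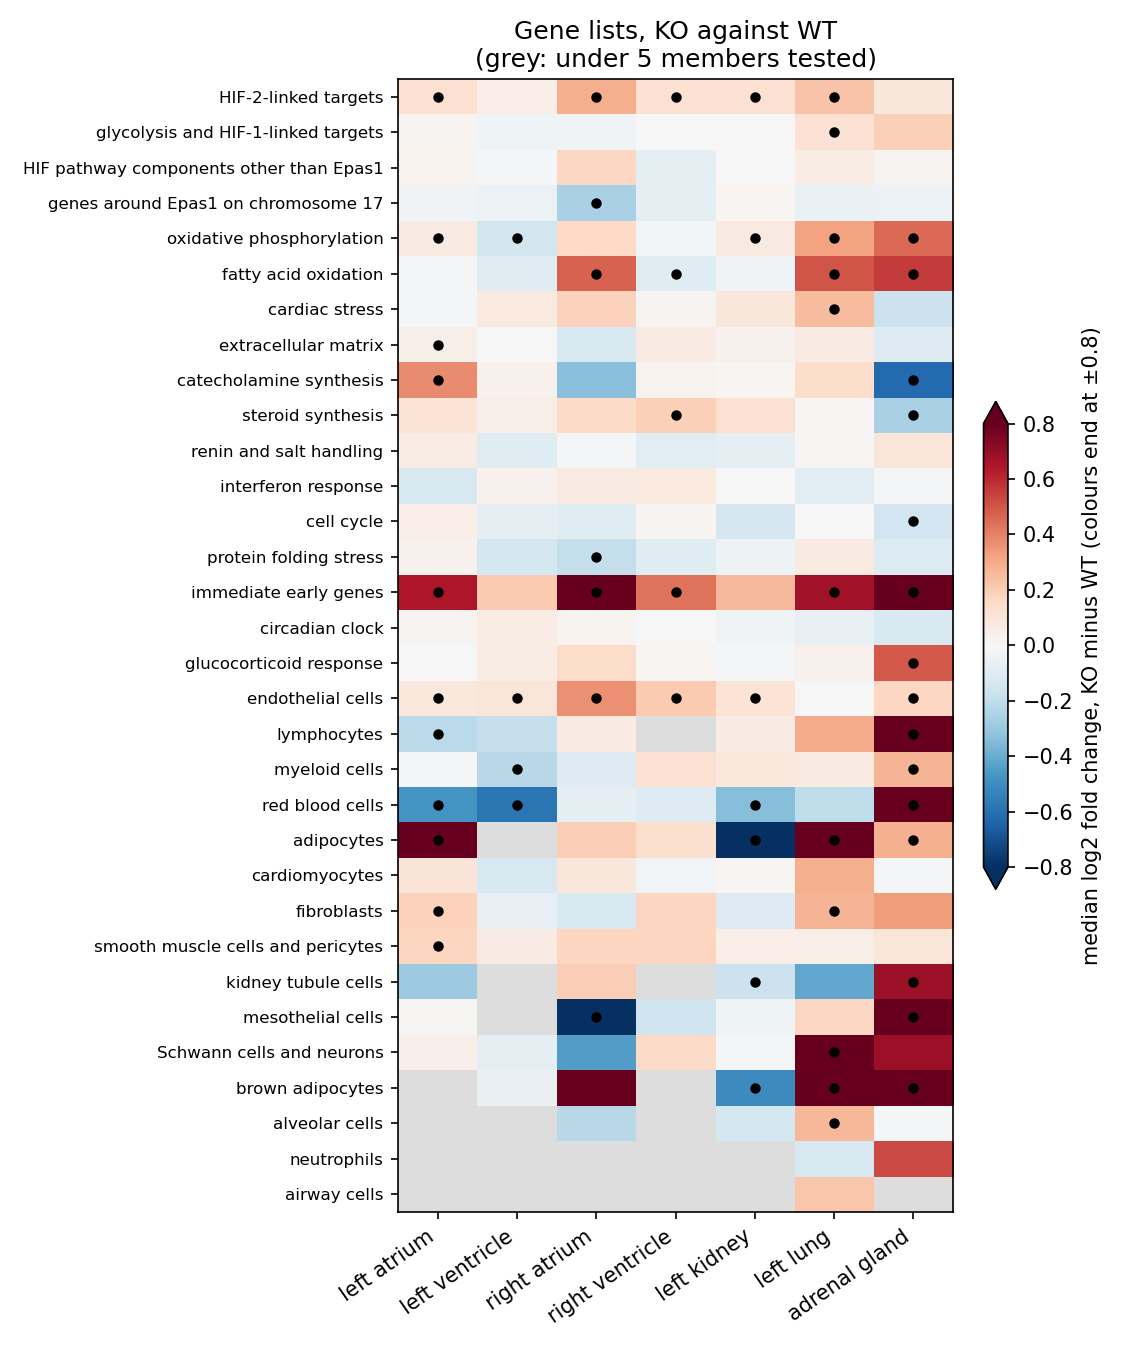
Median log2 fold change, KO minus WT, of each gene list (vertical axis) in each tissue (horizontal axis), on a color scale with higher in KO and lower in KO as its ends. Dots mark the 60 combinations past camera with the preset correlation, and grey cells had fewer than 5 members.

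In the left atrium, endothelial, fibroblast, smooth muscle and fat cell lists stood higher in KO. Cldn5 (chromosome 16, 18776847 to 18778262), a tight junction gene of endothelium, held 18.9 ± 2.12 CPM in KO and 10.4 ± 0.644 in WT (SD, n = 3 each), a log2 fold change of 0.86 ± 0.12 (SE). Pnmt, the enzyme that makes adrenaline, held 19.2 ± 2.67 and 8.71 ± 2.03 CPM, and Bdh1, a ketone body enzyme, 18.5 ± 1.88 and 11.3 ± 0.932. Among genes with a mean log2 CPM of at least 1, an ordinary symbol and no overlap of the genotypes, the conditions for naming a gene in each tissue, these 3 had the smallest p. They were not called by edgeR over all genes (adjusted p = 1), while DESeq2 called all 3 (adjusted p = 0.000128, 0.000698 and 0.00964). Adipocyte genes had a median of 1.71 (7 of 8 higher), with Plin1 at 2.21 ± 0.53, Cfd at 2.19 ± 0.65, Cidec at 1.95 ± 0.61 and Retn at 1.86 ± 0.61, and the median was 0.92 without KO201. Fibroblast genes had a median of 0.19 (10 of 10 higher, 0.12 without WT215), with Gsn at 0.29 and Dpt at 0.25. Smooth muscle cells and pericytes had 0.17 (9 of 10 higher, 0.27 without WT223), with Cnn1 at 1.45 ± 0.34, and endothelial cells 0.084 (11 of 16 higher, 0.049 without WT215 and 0.15 without WT223). These 4 lists passed camera in every fit without 1 animal (adjusted p with all 6: 1.12e-08, 0.00036, 0.000123 and 0.00162). Each had an adjusted p = 0.702 with an estimated correlation. Adjusted over the list alone, edgeR called 4 adipocyte genes, Cnn1, Cldn5 and Pnmt.

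Another 7 lists of the left atrium passed camera with all 6 libraries but not without some animal, HIF-2-linked targets among them, and none held with an estimated correlation (adjusted p = 0.702 to 0.936). Immediate early genes, the first transcripts to rise after a stimulus, had a median of 0.65, with Fosb at 1.33, Egr1 at 1.09, Junb at 1.05 and Ier2 at 0.87, and 0.024 without KO201. Catecholamine synthesis had 0.38, and 0.25 without KO205. Oxidative phosphorylation had 0.069, and 0.039 without KO201 or 0.01 without WT221. Extracellular matrix had 0.049, and 0.011 without KO201 or 0.10 without WT223. Red blood cell genes stood lower at -0.48, and were at -0.32 without KO201 and 0.13 without WT221. Lymphocyte genes stood lower at -0.22, a call that was lost without any animal except KO201, with medians of -0.28 to -0.085. Of 17737 genes edgeR called 0 (424 at an unadjusted p under 0.05), DESeq2 7 (492) and limma-voom 0 (480), and the genotypes did not overlap in 7.65% of genes, where chance gives 10%.

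In the left ventricle, KO animals had lower medians for myeloid, red blood cell and oxidative phosphorylation genes and a higher one for endothelial genes. Myeloid genes had a median of -0.22 (11 of 12 lower), with the macrophage genes Adgre1 at -0.55, Lyz2 at -0.38 and Csf1r at -0.22, and -0.17 without WT221. Endothelial genes had 0.099 (14 of 16 higher), with Cldn5 at 0.42 ± 0.11, Plvap at 0.36 and Egfl7 at 0.20, and 0.046 without WT223. Red blood cell genes had -0.58 (8 of 8 lower), and -0.10 without WT221. Oxidative phosphorylation had -0.15 (30 of 31 lower), and -0.09 without KO205 and 0.081 without WT223. The left ventricle of WT223 stood apart, with a chi-square per gene of 109.7 to 253.5 against the other 5 left ventricles, where their own pairs had 11.0 to 92.6, and it had the highest share of mitochondrial counts in this tissue (33.3%, against 27.5% to 30.7%). The camera adjusted p was 0.000186, 0.00141, 5.76e-06 and 0.00141 in that order. Each call was lost without the animals given with its median, and none held with an estimated correlation (adjusted p = 0.702 to 0.924). The genes with the smallest p that met the naming conditions were Cldn5 (39.9 and 29.9 CPM in KO and WT), Aqp4 (8.05 and 5.75) and Abhd1 (7.58 and 5.33), none of them called. EdgeR called 0 of 16344 genes (217 at an unadjusted p under 0.05), DESeq2 2 (281) and limma-voom 2 (242). The genotypes did not overlap in 5.88% of genes, against 10% by chance.

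In the right atrium, mesothelial genes stood lower and endothelial genes higher in KO, with a library of ventricular profile among the KO libraries. Mesothelial genes, of the outer lining of the heart, had a median of -1.17 (7 of 7 lower), with Krt19 at -1.65, Msln at -1.34 and Muc16 at -1.25 (-1.17, -0.86 and -0.79 without KO205), and a median of -0.68 without KO205 or -2.13 without KO201. Endothelial genes had 0.36 (11 of 16 higher), with Cldn5 at 1.49 ± 0.47, Robo4 at 0.99 and Cdh5 at 0.74 (0.94, 0.57 and 0.32 without KO205), and a median of 0.21 without KO205. These passed camera in every fit without 1 animal (adjusted p with all 6: 1.05e-07 and 0.00239), and had an adjusted p = 0.702 with an estimated correlation. Fatty acid oxidation had 0.47 (25 of 25 higher), with Ucp3 at 1.65 and Cd36 at 0.80 (0.41 and -0.052 without KO205), and a median of -0.04 without KO205, whose share of mitochondrial counts was 27.6%, against 11.9% to 17.8% in the other 5. Immediate early genes had 0.95 (16 of 16 higher), with Egr1 at 1.47 and Dusp1 at 1.06 (1.96 and 1.30 without KO205), and a median of -0.0052 without KO201. Protein folding stress had -0.19, with Pdia4 at -0.49 (-0.40 without KO205), and a median of -0.21 without KO203, -0.14 without KO205 and -0.035 without WT221. None of these held with an estimated correlation (adjusted p = 0.749 to 0.887). The genes with the smallest p that met the naming conditions were Jak3 (17.7 and 10.5 CPM in KO and WT), Rrp12 (24.6 and 12.6) and H2-Q7 (25.3 and 9.17), which shares sequence with near-identical genes and is uncertain. Their log2 fold changes were 0.75, 0.97 and 1.47, and 0.61, 0.67 and 1.71 without KO205. None was called. EdgeR called 0 of 17851 genes (288 at an unadjusted p under 0.05, and 0 called with 186 without KO205), DESeq2 1 (617) and limma-voom 0 (230). The genotypes did not overlap in 5.94% of genes, against 10% by chance. The brown fat gene Ucp1 stood at 583 CPM in KO201, 84.7 in WT223 and 76.7 in WT215 of this tissue.

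In the right ventricle, immediate early and endothelial genes stood higher in KO. Immediate early genes had a median of 0.43 (16 of 16 higher), with Ccn1 at 0.80, Dusp1 at 0.58, Klf4 at 0.48 and Jun at 0.29, and 0.087 without KO201. Endothelial genes had 0.21 (16 of 16 higher), with Cldn5 at 0.60, Eng at 0.42 and Egfl7 at 0.40, and -0.047 without KO201 or 0.22 without WT223. Fatty acid oxidation had -0.098 (22 of 25 lower), and 0.05 without KO201 or -0.05 without WT223. Steroid synthesis genes had 0.19 (7 of 8 higher), a call lost without any animal except KO205, with medians of 0.15 to 0.24. Camera gave adjusted p of 4.15e-06, 0.0002, 0.00583 and 0.0247, each lost without the animals named. None held with an estimated correlation (adjusted p = 0.702 to 0.924). The genes with the smallest p that met the naming conditions were Irx5, a transcription factor of the ventricular wall (2.20 and 3.97 CPM in KO and WT), Pim1 (26.7 and 18.5) and the endothelial factor Sox18 (42.9 and 26.6), none of them called. Of 15897 genes edgeR called 0 (138 at an unadjusted p under 0.05), DESeq2 3 (281) and limma-voom 0 (161). The genotypes did not overlap in 4.13% of genes, against 10% by chance. Without the filter on low counts edgeR called 56 genes, 46 of them highest in KO205, among them Alb, Apoa1 and Ttr, genes known from liver and picked here after their values were seen. Alb stood at 201 CPM in that library when scaled over all 42 libraries, and at 150.1 CPM in the fit without a filter.

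In the kidney, fat cell genes stood lower in KO, and so did tubule genes. Adipocyte genes had a median of -1.26 (8 of 8 lower), with Retn at -1.89, Adipoq at -1.53 and Cidec at -1.37, and -0.67 without WT223. Brown adipocyte genes had -0.51, with Dio2 at -2.26, and 0.076 without KO201 or 0.053 without WT223. Tubule genes had -0.17 (8 of 12 lower), and -0.13 without KO205, -0.14 without WT215 or -0.018 without WT223. The endocytic receptor gene of the proximal tubule, Lrp2, held 498 ± 2.14 CPM in KO and 690 ± 33.6 in WT (SD, n = 3 each; log2 fold change -0.47 ± 0.094 SE), and its partner Cubn was at -0.36. EdgeR called both adjusted over the list alone and neither over all genes. Oxidative phosphorylation had 0.072, and 0.0063 without KO201 or 0.0037 without WT221, and the share of mitochondrial counts was 18.0% to 18.6% in KO and 16.0% to 17.7% in WT. Endothelial genes had 0.11, and 0.084 without KO203 or 0.014 without WT215. Red blood cell genes had -0.34, and -0.14 without KO203 or -0.019 without WT221. Camera gave adjusted p of 5.43e-08, 0.00223, 0.00968, 0.00285, 0.00432 and 0.0112 in that order, each lost without the animals named. None held with an estimated correlation (adjusted p = 0.702 to 0.924). Trf, the transferrin gene, held 20.8 CPM in KO and 35.1 in WT and was not called. Serpina1c held 8.99 and 5.70 and was not called, and it shares reads with near-identical genes. Among 18266 genes edgeR called 0 (233 at an unadjusted p under 0.05), DESeq2 1 (335) and limma-voom 0 (286), and the genotypes did not overlap in 5.21% of genes, against 10% by chance.

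In the lung, KO animals had higher medians for oxidative phosphorylation and immediate early genes. Oxidative phosphorylation had a median of 0.32 (31 of 31 higher), with Sdhd at 0.52, Sdhb at 0.51 and Ndufv1 at 0.45, and 0.11 without KO203. Immediate early genes had 0.67 (14 of 16 higher), with Fos at 1.15, Junb at 0.96, Btg2 at 0.86 and Ier2 at 0.72 ± 0.17, and 0.39 without WT221. Both passed camera in every fit without 1 animal (adjusted p with all 6: 6.35e-11 and 5.05e-11). With an estimated correlation the adjusted p was 0.777 and 0.702. Adjusted over the list alone, edgeR called Ier2 and Junb, and over all genes neither. Alveolar genes had 0.27 (10 of 12 higher), with the surface markers Pdpn at 0.53 and Ager at 0.43 and the surfactant gene Sftpd at 0.37, and 0.20 without WT223. Fat and nerve lists moved most with 1 library, KO203, whose Ucp1 stood at 89.0 CPM (136.7 in the lung fit without a filter). Adipocyte genes had 1.34, and 1.27 without WT221, while without KO203 it was -0.30 and passed camera in the other direction (adjusted p = 0.00975). Brown adipocyte genes had 1.70, with Ucp1 at 9.07 ± 2.75 and Cidea at 4.17 ± 1.38 called adjusted over the list alone, and 0.029 without KO203. This call was made again in only 2 of the 6 fits without 1 animal, since in some of them the list was not tested. Schwann cell and neuron genes had 0.99, and 0.046 without KO203. Fatty acid oxidation had 0.50, and 0.052 without KO203. Fibroblast genes had 0.27, and 0.13 without KO203 or 0.14 without WT215. Cardiac stress genes had 0.25, and 0.21 without KO203 or 0.20 without WT221. From the alveolar list on, camera gave adjusted p of 0.000142, 0.00183, 0.013, 0.000473, 1.27e-07, 0.007 and 0.0137, each lost without the animals named. None held with an estimated correlation (adjusted p = 0.702 to 0.863).

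The lung genes with the smallest p that met the naming conditions were Peg3, an imprinted gene (31.7 CPM in KO and 56.1 in WT), Ier2 (105.6 and 64.0) and Srp54b (14.0 and 7.81), which has near-identical copies and is uncertain. None was called (edgeR adjusted p = 0.977). EdgeR called 0 of 19199 lung genes (536 at an unadjusted p under 0.05), DESeq2 6 (701) and limma-voom 0 (546). The genotypes did not overlap in 7.58% of genes, against 10% by chance. Without the filter on low counts edgeR called 28 genes, 13 of them highest in KO203, Ucp1, Cidea and Elovl3 among them.

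In the adrenal gland, catecholamine genes stood lower in KO, while oxidative phosphorylation, fatty acid oxidation, lymphocyte and mesothelial genes stood higher. Catecholamine synthesis had a median of -0.62 (11 of 13 lower). Its secretory granule gene Chgb held 1678 CPM in KO and 2932 in WT (log2 fold change -0.81 ± 0.18 SE, n = 3 each), and Th, the first enzyme of the pathway, 121 and 189 (-0.64 ± 0.21). Chga was at -0.77 ± 0.21 and Dbh at -0.62 ± 0.19. Oxidative phosphorylation had 0.45 (31 of 31 higher), with Sdhd at 0.67 and Cox5a at 0.67. Fatty acid oxidation had 0.56 (24 of 25 higher), with Acaa2 at 0.79 and Etfb at 0.73, and 0.37 without WT223. The share of mitochondrial counts was higher in every KO library (15.7%, 16.2% and 20.6%) than in every WT one (12.8%, 13.9% and 14.3%). Lymphocyte genes had 1.43 (12 of 12 higher), with the B cell genes Cd79a at 2.25 and Cd79b at 2.12, and 0.59 without KO201. Mesothelial genes had 1.06 (7 of 7 higher), with Upk1b at 1.67 and Upk3b at 1.64, and 0.50 without KO201. These 5 passed camera in every fit without 1 animal (adjusted p with all 6: 2.97e-05, 1.12e-15, 5.07e-11, 1.34e-06 and 0.000423). With an estimated correlation the adjusted p was 0.725 for lymphocytes and 0.702 for the other 4. The adrenal libraries differed in other material. Ucp1 lay between 27.9 CPM in WT223 and 834 in KO201. The liver gene Alb was at 15580 CPM in KO203, 5178 in WT223 and 192 in KO201, against 7.84 or less in the other 3. The muscle gene Acta1 was at 1098 CPM in KO201 and 1494 in WT223.

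Another 10 adrenal lists passed camera with all 6 libraries but not without some animal, and none of them held with an estimated correlation (adjusted p = 0.702 to 0.887). Steroid synthesis had a median of -0.26 (14 of 15 lower), with the steroidogenic factor Nr5a1 at -0.48, the corticotropin receptor gene Mc2r at -0.42 and Cyp21a1 at -0.42, while Por was at 0.67. It was at -0.21 without KO203, -0.25 without KO205 and -0.14 without WT223. Immediate early genes had 0.92, with Fos at 2.01 and Junb at 1.84, and 0.47 without KO201 or 0.55 without WT223. Glucocorticoid response genes had 0.49, with Angptl4 at 0.88 ± 0.18 called adjusted over the list alone, and 0.03 without KO201, 0.27 without KO203, 0.29 without WT215 or 0.26 without WT221. Brown adipocyte genes had 1.05, with Ucp1 at 1.44, and 0.55 without KO201. Adipocyte genes had 0.28, and 0.23 without KO201, 0.11 without KO205, 0.34 without WT215 or -0.069 without WT223. Endothelial genes had 0.16, with Cldn5 at 1.00 ± 0.24, and 0.08 without KO201, 0.25 without KO205 or 0.14 without WT215. Myeloid genes had 0.27, and 0.12 without KO201, 0.22 without KO205 or 0.24 without WT223. Red blood cell genes had 0.81, and -0.02 without KO203, 0.35 without WT215 or 0.50 without WT223. Kidney tubule genes had 0.68, and 0.15 without KO205, 0.77 without WT215 or 0.55 without WT223. Cell cycle genes had -0.15, with Mki67 at -0.55, and -0.27 without KO203, -0.15 without KO205 or -0.18 without WT223.

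Single adrenal genes with the smallest p that met the naming conditions were Tmem130 (16.6 CPM in KO and 30.9 in WT, log2 fold change -0.90 ± 0.15 SE), the prohormone convertase gene Pcsk1 (25.1 and 48.3, -0.95 ± 0.16) and Adcyap1r1, a receptor of the splanchnic nerve transmitter PACAP (60.9 and 87.2, -0.52 ± 0.095). None was called by edgeR (adjusted p = 0.983). Among 18310 genes edgeR called 0 (772 at an unadjusted p under 0.05), limma-voom 0 (749) and DESeq2 22 (1158), 11 higher and 11 lower. Among the 11 lower by DESeq2 were Pcsk1, Tmem130, Chgb (-0.80) and Scg2 (-0.77), each with an adjusted p of 0.00888. Among the 11 higher were Rasd1 (1.60, adjusted p = 0.0278), Ppargc1b (1.16, 0.0168) and Angptl4 (0.89, 0.0406). Chgb, Scg2, Rasd1, Ppargc1b and Angptl4 were picked here after their DESeq2 values were seen. The genotypes did not overlap in 10.1% of genes, against 10% by chance. Named here for the same reason, the DESeq2 calls were the gene models Rpl36a-ps3 and Gm13328 in the left ventricle, Gm28778 in the right atrium and Gm2436 in the kidney. Their values are uncertain where they share sequence with other genes. In the right ventricle the calls were Rdh7 (21.23), Plg (21.098) and Gm49361 (21.066), which edgeR's filter had removed. Rdh7 had counts in 1 right ventricular library only, KO205 (1.742 CPM in the fit without a filter), the library in which Alb stood at 150.1 CPM.

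Over the 7 tissues of each animal taken as a mean, Cldn5 was higher in KO by 0.64 ± 0.11 (log2, SE, n = 3 animals each), Angptl4 by 0.56 ± 0.12 and Plk2 by 0.57 ± 0.13. None of the 3 was called by limma (adjusted p = 1). Limma called 0 of 22794 genes (405 at an unadjusted p under 0.05), edgeR on counts summed per animal 0 (617) and limma-voom with a random animal effect 0 (342). The interaction of genotype and tissue, tested by edgeR, called 0 of 22794 genes (564 at an unadjusted p under 0.05). Its smallest p belonged to Scg5, a secretory granule gene (log2 fold change -0.63 in the left atrium, 0.84 in the lung and -0.56 in the adrenal gland). The chaperone gene Hsph1 followed, from 0.39 in the left ventricle to -1.10 in the adrenal gland. Pnmt was at 1.15 in the left atrium and -0.68 in the adrenal gland, and Cd79b at 2.12 in the adrenal gland and -1.31 in the right atrium (-1.13 without KO205). Scn3a and Myo19 were highest in the right atrium, at 2.34 and 1.12 (0.95 and 0.62 there without KO205). Sec61a2 ranged from -0.46 to 0.22, Tubb6 from -0.30 to 0.43 and Pamr1 from -0.73 to 0.58. Kcnq1ot1 was at -1.12 in the lung, where its reads cannot be separated from those of the gene on the other strand. The adjusted p of all 10 was 1.

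The left atrium differed from the right in 612 of 17518 genes by edgeR with the animal as a block, 296 higher on the left and 316 on the right (3204 at an unadjusted p under 0.05, 12 libraries). Bmp10 (chromosome 6, 87428994 to 87437677), a growth factor of the right atrium, held 0.318 CPM on the left and 2515 on the right (log2 fold change -12.54 ± 1.56 SE; adjusted p = 0.00828). Without KO205 it held 0.331 and 3081 CPM (-13.22 ± 0.58, adjusted p = 1.86e-05). Among the genes higher on the left were Adamts8 (3.11 ± 0.31), Tnni2 (2.78) and Mmrn1 (2.72). Among the others higher on the right were Ucp1 (-10.26 ± 1.09), Adig (-5.47), Myoc (-3.88) and Itgal (-3.82). Of 612 genes, 579 moved the same way in every animal. The count was 150 without KO201, 153 without KO203, 2275 without KO205, 133 without WT215, 433 without WT221 and 201 without WT223. All 612 were among the 2275, in the same direction.

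Fibroblast genes were higher in the left atrium, 5 of 10 with 0 on the right, among them Pi16 (2.13), Mfap5 (0.85) and Col15a1 (0.82). Of 30 HIF-2-linked targets 7 were higher on the right and 2 on the left (10 and 2 adjusted over the list alone), with Egln3 at -1.26, Ndufa4l2 at -1.04 and Slc40a1 at 0.91. Of 29 glycolysis and HIF-1-linked targets 4 were higher on the right (10 adjusted over the list alone), with Slc2a1 at -0.70, Pfkl at -0.67 and Bnip3 at -0.64. Catecholamine genes higher on the left were Slc6a2 (3.40), Pnmt (2.09) and Slc18a2 (0.89), 3 of 7. Extracellular matrix genes higher on the left were Mmp2 (1.57) and Lox (0.58), 2 of 17. Of 12 myeloid genes Cd14 (-1.08) and Ccr2 (-1.25) were higher on the right and Mrc1 (0.63) on the left. Of the cardiac stress genes Ccn2 (1.00) was higher on the left and Ankrd1 (-1.08) on the right, and the smooth muscle gene Acta2 (-2.16) was higher on the right. Of 8 adipocyte genes edgeR called 0 over all genes and 6 on the right adjusted over the list alone, with a median of -3.71. Without KO205 it called 5 of them, and 7 of 25 fatty acid oxidation genes on the left, where it called 0 with all animals. Without KO205 the other counts on the left and right were 5 and 8 HIF-2-linked targets, 0 and 6 glycolysis genes, 5 and 1 fibroblast genes, 3 and 3 extracellular matrix genes (Timp1 at -0.89 and Col1a1 at -0.50 on the right) and 1 and 6 myeloid genes. Catecholamine genes, called only on the left with all animals (3 on the left and 2 on the right adjusted over the list alone), were then 3 on the left and 2 on the right of 8, with Th at -4.80 (edgeR adjusted p = 0.000911) and Dbh at -3.49 (adjusted p = 0.0052).

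The library labelled right atrium KO205 held Bmp10 and Myl2 within the ventricular range and 4 other chamber markers outside it, but nearer to it than to the other right atria. Its Bmp10 was at 6.08 CPM, against 2193 to 3757 in the other 5 right atrial libraries and 0.0225 to 17.6 in the 12 ventricular ones. Nppa, the atrial natriuretic peptide gene, was at 555 CPM, against 15920 to 33650 and 32.0 to 209.6. The atrial genes Myl7, at 52.9 CPM, and Sln, at 23.3, stood above the ventricular ones as well (at most 30.6 and 14.4) and below the right atrial ones (at least 2492 and 866). The ventricular myosin light chain gene Myl2 was at 5069 CPM, against 5.96 to 227 in right atria and 4735 to 10630 in ventricles. The ventricular factor Irx4 was at 18.04 CPM, against at most 0.849 in the other right atria and 18.15 to 27.8 in ventricles. Its correlation across genes, which are not independent replicates, was 0.970 to 0.984 with the 12 ventricular libraries and 0.941 to 0.960 with the other 11 atrial ones. The label was kept, and values without this library stand beside many of the right atrial results, though not beside all of them.

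**Figure D3:**
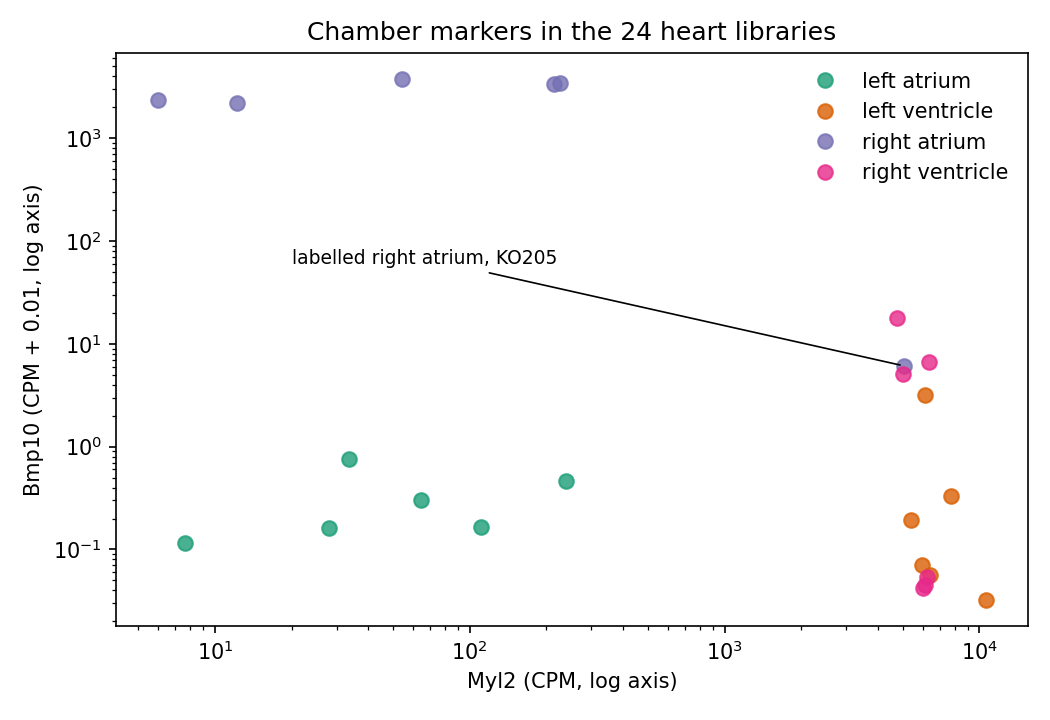
The ventricular gene Myl2 against the right atrial gene Bmp10, both in CPM on log axes, for the 24 heart libraries by chamber. The library labelled right atrium KO205, at 5069 CPM of Myl2 and 6.08 CPM of Bmp10, lies with the ventricles and apart from the other 5 right atria.

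The left ventricle differed from the right in 200 of 15948 genes, 98 higher on the left and 102 on the right (edgeR with the animal as a block, 2510 at an unadjusted p under 0.05). As for the atria, chamber and sequencing lane cannot be told apart in these differences. Acta1, the skeletal muscle actin gene that the stressed heart expresses, held 150.2 CPM on the left and 37.7 on the right (log2 fold change 2.32 ± 0.23 SE; adjusted p = 0.00127). It was 1 of 4 cardiac stress genes of 14 that were higher on the left, with Nppb (2.01) and Ankrd1 (1.14). Other genes higher on the left were small or ribosomal RNAs, Rn7sk (3.69 ± 0.47), CT010467.1 (2.58 ± 0.42), and Rn7s1 and Rn7s2 (3.35 ± 0.49), near-identical copies whose values were equal and are uncertain. Higher on the right were the mitochondrial gene mt-Co2 (-2.35 ± 0.18; 110.4 and 575 CPM; adjusted p = 0.00026), Cntn2, a marker of conduction fibres (-2.09), the Wnt inhibitor Wif1 (-1.97) and Ddc (-1.61). The share of all mitochondrial counts did not go with mt-Co2. It was 27.48% to 33.26% in the left ventricle and 24.12% to 29.15% in the right. The mt-Co2 difference is therefore uncertain, and how its reads were assigned was not tested. Mesothelial genes higher on the right were Msln (-2.48) and Upk3b (-2.49), 2 of 3, and endothelial genes Vwf (-0.96) and Plvap (-0.85), 2 of 16. Thrsp, of the adipocyte list, was higher on the left (0.48). Bmp10 did not pass the filter. Of the 28 HIF-2-linked targets and the 27 glycolysis genes edgeR called 0 over all genes, and 1 and 0 adjusted over the list alone. Of 200 genes 196 moved the same way in every animal. Without a single animal the count was 51 (WT221) to 141 (KO205), with 111 without KO203 and 86 without WT215, and without the animal block it was 65. Of the 141, 127 were among the 200.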

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

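No test was chosen after these results were seen, because neither of the differences below was tested. Steroid synthesis genes stood higher in every KO animal than in every WT animal in the right ventricle and lower in every KO animal than in every WT animal in the adrenal gland. The KO minus WT difference of the list's median was 0.136 in the right ventricle and -0.262 in the adrenal gland (log2), which lie 0.398 apart. The members tested were not the same in these tissues. Over the 7 members expressed in every organ, the genotypes overlapped in both tissues. In the right ventricle KO205 then stood at -0.105 and WT215 at 0.0127, and in the adrenal gland KO201 at 0.186 and WT215 at 0.053. Adipocyte genes stood higher in every KO animal in the left atrium, at 0.80 ± 0.80 in KO and -0.555 ± 0.505 in WT (log2, mean ± SD, n = 3 each), and lower in every KO animal in the kidney, at -1.04 ± 2.33 and 0.95 ± 0.73. These KO minus WT differences of 1.36 and -1.99 lie 3.35 apart. The KO and WT animals were fully apart in 16 of the 203 combinations of list and tissue, or 7.88%, where chance gives 10%.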

How the results depend on the processing

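The fits without the right atrium were chosen after seeing the data. No paired analysis was possible because the KO and WT mice were different animals and the labels do not say which of them shared a chamber. A sex term was not run, since all animals were male by expression. The count of called KO against WT genes was 0 by edgeR in every tissue. With DESeq2 it was 7 in the left atrium, 2 in the left ventricle, 1 in the right atrium, 3 in the right ventricle, 1 in the kidney, 6 in the lung and 22 in the adrenal gland. Without a filter it was 1 in the left ventricle, 56 in the right ventricle, 1 in the kidney and 28 in the lung. Limma-voom gave 2 in the left ventricle, TPM 2 in the lung, and 1 fit of all 42 libraries 1 in the lung. Without 1 animal each it stayed at 0, except in the left atrium (0 to 1). The cause was not tested, except that genes under the filter can be called only without it. That reason does not cover 13 of the 28 lung calls and 7 of the 56 right ventricular calls, which were genes that the filter kept. Nor does it cover the calls without a filter in the kidney and left ventricle. Animal means and interaction stayed at 0 under every alternative run, those without the right atrium included. Epas1 changed sign in the right ventricle in the fit of all 42 libraries (-0.0035), in the adrenal gland by TPM (-0.28), and in the mean of 7 tissues without the right atrium (-0.044) and by TPM (-0.062), and was past no threshold. Leaving out each animal moved Epas1 from -0.15 to 0.088 in the left atrium, -0.019 to 0.079 in the left ventricle, -0.10 to 0.14 in the right ventricle, -0.064 to 0.028 in the kidney and -0.092 to 0.081 in the mean. It kept its sign in the lung (-0.50 to -0.17), the right atrium (0.13 to 0.44) and the adrenal gland (0.024 to 0.16). The 60 calls of gene lists were 0 with an estimated correlation and 0 with fry, while the totals without 1 animal were 59 to 68, with 12 to 22 of the 60 lost in each. Of the 60, 13 were kept without each animal in turn. Among the list medians that changed sign or call, ranges were -0.76 to 0.13 (red blood cells, left atrium), -0.26 to 0.081 (oxidative phosphorylation, left ventricle), -0.040 to 0.69 (fatty acid oxidation, right atrium), -0.0052 to 1.25 (immediate early genes, right atrium), -0.20 to 0.050 (fatty acid oxidation, right ventricle), -0.048 to 0.21 (HIF-2-linked targets, right ventricle), -0.047 to 0.37 (endothelial cells, right ventricle), -0.50 to -0.019 (red blood cells, kidney), -0.96 to 0.076 (brown adipocytes, kidney), -0.30 to 1.79 (adipocytes, lung), 0.029 to 2.16 (brown adipocytes, lung), -0.020 to 2.18 (red blood cells, adrenal gland) and -0.069 to 0.61 (adipocytes, adrenal gland). Left against right atrium gave 612 genes, 402 in WT animals only (fewer samples and no library of KO205, so the cause was not tested) and 133 to 2275 without 1 animal. Left against right ventricle gave 200 genes, 65 with no replicate block, 996 without a filter (more genes tested), 34 in WT animals only and 51 to 141 without 1 animal. The block changed no other call by over 1.5 times. For single named genes and lists, 654 values under an alternative kept their direction and side of the threshold, 230 kept the direction but lost the call, 5 gained a call and 10 changed direction. Depth limits these results little, since the spread between animals exceeded counting error in all 42 pairs of libraries of a group.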

Other observations

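Tests chosen only after the results were seen are the splits of the libraries within each tissue, the tests of mixed tissue and of exchanged names for the library labelled right atrium KO205, its chi-square comparison with other libraries, the scores without the right atrium, and the tests of animal ranks over the tissues, those of immediate early and glucocorticoid-linked genes among them. The camera tests of these lists were planned.

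Single animals differed from the rest in the same direction in organ after organ. Glucocorticoid-linked genes, which corticosterone is known to induce, were highest in WT223 (0.61, mean over 7 tissues of the list's median deviation from the tissue mean, log2) and KO201 (0.54), and lowest in WT221 (-0.50), KO205 (-0.355) and WT215 (-0.29). The ranks of the 6 animals over the 7 tissues had a Kendall W of 0.935 (permutation p = 1e-05, the smallest that the resamples can give, adjusted p = 5.25e-05 over 21 lists). Zbtb16 deviated by 1.24 in WT223, 0.87 in KO201 and -1.14 in WT221, and the W of Klf9, Fkbp5, Per1 and Tsc22d3 was 0.93, 0.911, 0.9 and 0.86. Among 2000 random lists of the same size the median W was 0.321 and the highest 0.865. Only list members expressed in every organ were scored. Circadian clock genes had a W of 0.958 (15 members), cardiac stress genes 0.771 (5), steroid synthesis genes 0.608 (7) and protein folding genes 0.578 (13). In the mean over tissues the clock genes put the 6 animals in the same order as the glucocorticoid-linked genes. That order ran from WT223 (0.363) and KO201 (0.172) down to KO205 (-0.197) and WT221 (-0.335), so it was not particular to the glucocorticoid list. Red blood cell genes had a W of 0.499 (6 members) and were highest in WT221 (0.89). HIF-2-linked targets had a W of 0.478, and their KO minus WT difference had an exact permutation p of 0.2. Besides the glucocorticoid list, only the immediate early genes were set against random lists. The W of the other lists is thus not shown to exceed that of random genes. Endothelial genes stood higher in every KO than in every WT animal in the mean over tissues, by 0.13, and oxidative phosphorylation genes by 0.12 (exact permutation p = 0.1 for each, the smallest possible, among 21 lists). Neither stayed apart without the right atrium, where the differences were 0.10 and 0.12 (exact permutation p = 0.2 for each). Smooth muscle cell and pericyte genes were fully apart only without the right atrium, higher in KO by 0.086 (exact permutation p = 0.1, and 0.2 with the right atrium).

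The ventricular profile of the library labelled right atrium KO205 was set against mixed and exchanged tissue. An atrial sample with some ventricle in it would keep part of its Bmp10, but the library held 0.201% of the mean of the other 5 right atria, which argues against that. Nppa, Myl7 and Sln, at 555, 52.9 and 23.3 CPM, stood above every ventricular library (at most 209.6, 30.6 and 14.4) and below every other atrial one (at least 15920, 2492 and 866), so a small atrial part in ventricular tissue stays open. An exchange of names with a ventricular library of the series would put high Bmp10 in a ventricular library, but the highest of the 12 held 17.6 CPM. Its deviations from the ventricular mean correlated best with those of KO205 in other organs (0.438 over 12047 genes), but by only 0.0453 over the next animal, WT221, so ventricular tissue of KO205 may be the source while another animal stays open. By chi-square per gene its nearest libraries were the left (20.5) and right (25.9) ventricle of KO205, before the left ventricle of WT215 (36.7). This goes with KO205 but does not settle the animal, since by the same measure the nearest ventricle of the other side was the animal's own for 5 of the 12 ventricular libraries and that of KO205 for 4 libraries of other animals. No biological explanation was tested.

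Immediate early genes passed camera with the preset correlation as higher in KO in 5 tissues. With an estimated correlation they passed in none (smallest adjusted p = 0.702). In 0 tissues did every KO animal stand above every WT animal. That count cannot decide on a shift shared by the KO animals, because a single low KO animal is enough to give it. KO205 stood below the tissue mean in every tissue (-0.765 to -0.152). KO201 (0.357 to 1.42) and KO203 (0.0911 to 0.993) stood above it in every tissue. By these genes, the ranks of the 6 animals over tissues had a Kendall W of 0.799. Among 2000 random lists of the same size 14 reached as much. KO201 stood at 0.84 and KO203 at 0.47, while KO205 was at -0.53, WT215 at 0.086, WT221 at -0.30 and WT223 at -0.38. A candidate explanation is a state of single animals that their organs share, such as the handling before death, which the labels do not record per animal. The KO minus WT difference over the animals had an exact permutation p of 0.4.

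For the glucocorticoid-linked genes, a trend with transcript length was tested as a technical explanation, and the W was 0.958 after that trend was removed from every library, which argues against it. Genotype is argued against as well, since in 7 tissues a KO and a WT animal stood above the tissue mean and a KO and a WT animal below it. A shared chamber run may account for the pattern, since each run held 1 KO and 1 WT mouse. The KO and WT animals that deviated together most were KO201 and WT223, with a mean correlation of 0.489 across genes over the tissues, but the pairs are not named in the labels and this pair was picked as the highest, so the explanation stays open. No animal was regrouped by this measure.

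Other splits of the 6 animals were set beside each KO against WT result. With 10 splits in all, they are too few for a share under 0.05. The real count of called genes was 0 in each tissue, and the highest count of another split was 0 in the left atrium, left ventricle, right atrium and kidney, 1 in the right ventricle and adrenal gland, and 5 in the lung. For the animal means the real count was 0 and the highest other 2. For the interaction the real count was 0 and the highest other 828, in the split that set KO201, KO203 and WT223 against the rest, and such a count points to a structure of the samples. The same split gave the most genes at an unadjusted p under 0.05 in 6 of the 7 tissues, 4013 against the real 536 in the lung and 3782 against 424 in the left atrium. For the gene lists the real count was 60 and the highest other 81, and 6 of the 10 splits gave 60 or more. For left against right atrium 2 of 32 exchanges of the sides within animals gave 612 genes or more, the real one and the exchange in KO205 with 652, so this count alone does not exclude chance at a share of 0.05. The other exchange turns the sides of the animal whose right atrial library had a ventricular profile, and without KO205 the fit called 2275 genes with all 612 among them in the same direction. For left against right ventricle 1 of 32 exchanges, the real one, reached 200 genes, and the highest other count was 1 gene. This share is the smallest that the exchanges can give, and it argues against a chance assignment of sides within animals. Chamber and sequencing lane cannot be told apart by such exchanges.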
